A study of Mus musculus with 27 samples.

How the data were processed

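Polysome-bound RNA from the prostates of mice of 6 genotypes was measured by RNA sequencing, with 3 mice per genotype, and total RNA was measured in 3 of the genotypes, which gave 18 polysome and 9 total RNA libraries. Per the labels, the mice were C57BL/6 animals of 20 to 25 weeks, the tissue was lysed in a buffer with cycloheximide, which holds ribosomes on the mRNA, and cytoplasmic extracts were separated on a gradient of 15 to 50% sucrose. RNA was then extracted from the polysomal fractions, and total RNA was extracted alongside. Per the labels' protocols, ribosomal RNA was depleted and strand-specific libraries were made from random primers (TruSeq stranded total RNA with Ribo-Zero Plus) and sequenced on a NextSeq 500.

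The deposited table holds whole-number read counts per gene, which the authors left unnormalised, for 54838 mouse gene identifiers in 27 libraries. Per the submitters' processing notes, reads were handled with FastQC, STAR 2.5.2a, DESeq and DESeq2 on the GRCm38 (mm10) build. The counting tool, its strand setting and the annotation release are not given in the sources used here. Identifiers were matched to GENCODE M21 for symbols, gene types and GRCm38 coordinates: 54809 matched and 29 did not, and the unmatched rows held at most 0.0118% of any library. A further 14462 genes had no count in any library. Library totals ran from 13352451 to 54120178 counts. Floors given in the text cover counting error only, and reads carried no molecular identifiers.

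Several steps upstream could change the measurements. Without a stated strand setting, reads of a gene and its antisense partner cannot be separated. Reads of near-identical copies may have been dropped or shared, so values of pseudogenes, ribosomal protein genes, the seminal vesicle secretory family, secretoglobins, kallikreins and replication-dependent histones are uncertain at the level of the single gene. Random priming keeps RNAs without a poly(A) tail, so small structural RNAs and histone transcripts entered the counts. Equal amounts of RNA were loaded on each gradient, so a change of all polysomal RNA together would leave no trace in these values. Prostate tissue was taken whole, so a count mixes all cell types of the sample.

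Counts were tested with edgeR 4.0.16 in R 4.3.3 with limma 3.58.1. Genes were kept by edgeR's filter on low counts, libraries were scaled by TMM, and quasi-likelihood models with robust estimation were fitted to group means. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene was called at an adjusted p below 0.05. The 5 comparisons of polysome-bound RNA came from 1 fit over the 18 polysome libraries (19087 genes tested). The comparisons of polysome-bound with total RNA within a genotype, of total RNA between genotypes, and of the polysome-to-total ratio between genotypes (an interaction term, called translation here) came from 1 fit over the 18 libraries of the Erg, Cdcp1 and Timp1 groups (17957 genes tested). Fold changes are log2 values with a prior count of 0.125, and errors beside them are standard errors. Where all libraries of a group were at 0, the fold is a lower bound against a floor of 3 counts over the group. Levels are given as counts per 1e6 counts of the library (CPM).

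Gene lists for cell types, pathways and RNA classes, 39 in all, were fixed before the data were examined, together with the groups, the tests, most other settings tried and the rule for named genes. Each list was tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, and p-values were adjusted over the lists. Camera sets a list against the other genes, and fry tests whether its members moved, on balance, one way. The genes named are the 5 targeted genes and, per comparison, those that passed the test with a mean raw count of at least 50, showed no overlap between the libraries of the groups compared and had a symbol that is not a clone name: the 10 with the largest rise and the 10 with the largest fall (5 and 5 for total RNA and translation). For each list described, up to 4 members with the smallest adjusted p were eligible. Counts of list members with each library left out were made for Pten against wild type alone, after the data were seen. Some of the eligible genes were left out of the text where their call ended without 1 library.

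Replicates were first compared for duplicates with a chi-square statistic of their counts, and no pair within a group lay near sampling noise (the lowest value was 11.4 per degree of freedom). Polysome and total RNA libraries with the same number in their titles come from the same mouse. The check of this pairing gave correlations of their deviations from the group means of 0.37 to 0.80 over the 9 mice. It separated Erg mice 1 and 3 only weakly, with 0.55 and 0.47 for their own pairs. Erg polysome 1 with total 3 gave 0.36, and polysome 3 with total 1 gave 0.46. The models without a mouse term were the main ones, and models with the mouse as a block were an alternative. Of the pairs of genotypes that share 3 numbers, which are Pten, Timp1 and Cdcp1 in polysome-bound RNA and Timp1 and Cdcp1 in total RNA, only the last deviated together in every pair of libraries (correlations of 0.25, 0.11 and 0.22).

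Other settings tried were other scalings (RLE and upper quartile), no filter and a filter at 1 CPM, non-robust estimation, all 27 libraries in 1 fit, only the groups compared, protein-coding genes only, the replicate block, each library left out in turn, and DESeq2 1.42.0. Settings added after seeing the data removed the seminal vesicle genes with their 50 closest correlates, or both libraries of 1 mouse, or fitted 1 genotype alone. The models without a mouse term were tested on simulated data drawn from the means, dispersions and library sizes of the real libraries with 200 genes changed. Models with the mouse as a block were tested at a low dispersion of 0.05 alone. Camera at the preset correlation was run on simulated lists too, in which genes varied independently of each other. Camera with an estimated correlation, fry, and the block fits without 1 mouse or within 1 genotype were not tested on simulated data. For Pten against wild type, 10 of 100 genes changed 2-fold and 58 of 100 changed 4-fold were called among 18596 genes tested, with 6 false calls. For Erg against Pten these numbers were 9 and 62 (18583 genes), for Trp53 against Pten 5 and 67 (18618 genes), for Cdcp1 against Pten 7 and 71 (18573 genes), and for Timp1 against Pten 6 and 67 (18597 genes). Polysome against total RNA gave 42 and 90 in the Erg group (17483 genes), 36 and 85 in the Cdcp1 group (17380 genes) and 35 and 91 in the Timp1 group (17370 genes). The translation comparisons gave 9 and 63 for Cdcp1 against Erg (17358 genes), 9 and 66 for Timp1 against Erg (17492 genes), and 11 and 62 for Timp1 against Cdcp1 (17451 genes). Figures and tables of members were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.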

Results

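Polysome-bound RNA, the RNA carried by several ribosomes at once, was sequenced from the prostates of mice of 6 genotypes, with 3 mice each. The genotypes were wild type, loss of Pten, and loss of Pten together with loss of Trp53, loss of Timp1, the TMPRSS2-ERG fusion or a change of Cdcp1. The last 4 groups are called Trp53, Timp1, Erg and Cdcp1. Total RNA of the same mice was sequenced for the Erg, Cdcp1 and Timp1 groups, which gave 27 libraries with totals of 13352451 to 54120178 counts. The submitters' labels are at odds for Cdcp1: the genotype field of each sample reads as a loss and the design text as a gain. Those libraries are therefore called the libraries labelled Cdcp1. Values are log2 fold changes ± SE with n = 3 per group unless stated, and coordinates are on GRCm38. Adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

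The targeted genes were read first. Pten (chromosome 19, 32757497 to 32826160) fell by 1.40 ± 0.36 in Pten against wild type (adjusted p = 0.00839). Its plain levels were 151 ± 47.2 and 254 ± 81.9 CPM (SD, n = 3). The level was 234 ± 65.5 CPM in Trp53, 218 ± 43.4 in Timp1, 261 ± 106 in the libraries labelled Cdcp1 and 183 ± 22.7 in Erg. Plain levels are not scaled by TMM, and those of Pten and wild type overlapped (189 CPM in Pten 1, 171 in wild-type 6). TMM factors were 0.665 to 0.872 in wild type and 1.05 to 1.19 in Pten, so part of the fall came from the scaling. Counts cover the whole gene and do not isolate a deleted part. Trp53 (chromosome 11, 69580359 to 69591873), which encodes the tumour suppressor p53, fell by 1.39 ± 0.31 in Trp53 against Pten (adjusted p = 0.00229), from 39.9 ± 2.94 to 16.2 ± 2.67 CPM. Erg (chromosome 16, 95359169 to 95586593), an ETS transcription factor, rose by 3.93 ± 0.32 in Erg against Pten (adjusted p = 1.7e-05), from 2.18 ± 0.533 to 28.7 ± 1.51 CPM. It also rose in Trp53 against Pten, by 2.48 ± 0.30 (adjusted p = 2.4e-05). Cdcp1 (chromosome 9, 123170824 to 123216038), a transmembrane Src substrate, stood at 114 ± 7.06 CPM in the polysome libraries labelled Cdcp1 and 131 ± 22.4 in Pten. The log2 difference was −0.06 ± 0.45 (adjusted p = 0.952), and its sign changed with upper quartile scaling (0.04), protein-coding genes only (0.01) and without Pten library 1 (0.05). In total RNA Cdcp1 fell by 0.65 ± 0.22 in these libraries against Erg (adjusted p = 0.0317). In total RNA of Timp1 against these libraries it differed by 0.37 ± 0.22, which did not pass (adjusted p = 0.265). Whether the label means a loss or a gain was left open. Timp1 (chromosome X, 20870166 to 20874735), an inhibitor of matrix metalloproteinases, stood at 2.17 ± 0.113 CPM in Timp1 and 56.0 ± 36.8 in Pten. The log2 difference of −4.42 ± 0.72 did not pass (adjusted p = 0.137). For Timp1 in Timp1 vs Pten the alternatives gave adjusted p from 1.5e-27 without a filter to 0.874 without Timp1 library 2, and DESeq2 gave 2.5e-08. In total RNA Timp1 fell by 3.18 ± 0.73 against Erg (adjusted p = 0.00901).

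**Figure D1:**
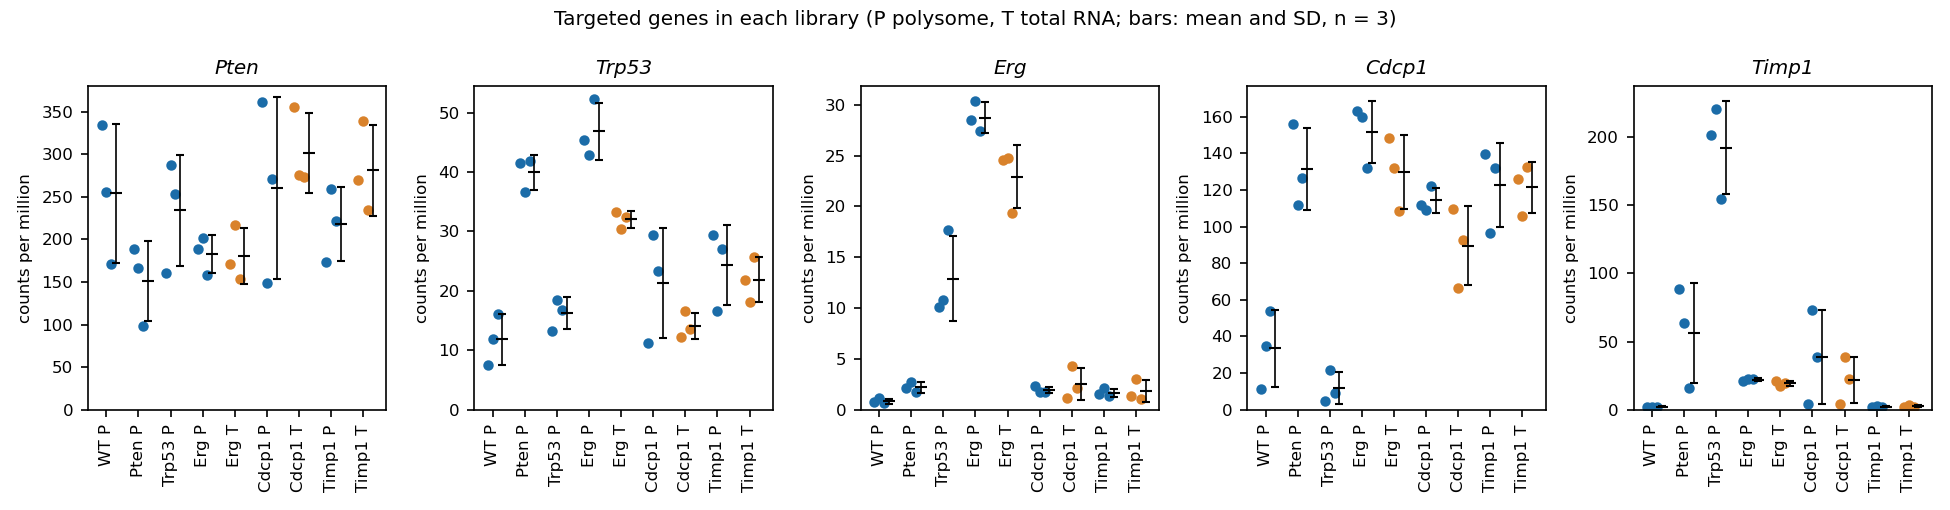
Levels (CPM) of the 5 targeted genes in each library, 1 panel per gene, with the 9 groups on the horizontal axis, polysome libraries in blue and total RNA in orange, and bars for the mean and SD of 3 libraries. Timp1 lies at 2.17 CPM in the Timp1 polysome group and at 193 CPM in Trp53, and Erg at 28.7 CPM in the Erg polysome group.

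Pten was compared with wild type in polysome-bound RNA, where the libraries differed in seminal vesicle RNA and in secretory genes beside the genotype. Several genes of the differentiated luminal cell fell. Nkx3-1, a homeobox factor of prostate identity (chromosome 14, 69190638 to 69194662), fell by 7.51 ± 0.88 (adjusted p = 3.9e-05). Msmb, a secreted prostate protein (chromosome 14, 32142023 to 32158370), fell by 7.39 ± 0.94 (adjusted p = 1.1e-04), and Pbsn, the androgen-regulated probasin (chromosome X, 77837901 to 77853623), fell by 9.14 ± 1.88 (adjusted p = 0.00258). Genes of luminal progenitors rose, with the keratin Krt6a up by 5.48 ± 0.78 and lactotransferrin, Ltf, up by 9.74 ± 1.09. Muc1, a membrane mucin, rose by 7.13 ± 0.71 (adjusted p = 1.2e-05), and Car9, a carbonic anhydrase induced by hypoxia, by 7.34 ± 0.73 (adjusted p = 1.3e-05). Cldn2, a tight junction protein (chromosome X, 139800828 to 139811386), was at least 1112-fold higher. Seminal vesicle secretory genes rose most, such as Svs2 (chromosome 2, 164235929 to 164238466) at 13.93 ± 2.89 (adjusted p = 0.00215) and Svs4 (chromosome 2, 164275952 to 164278459) at 13.22 ± 2.53. The fall of Rapgef4os3 (chromosome 2, 72244965 to 72248975), at least 597-fold, is uncertain because this RNA lies antisense to Rapgef4. In all, 6128 of 19087 genes were called, 3319 up and 2809 down, with 1666, 1785 and 1753 down without Pten 1, Pten 2 and wild-type 10. Of these, 4119 were abundant, free of overlap between the libraries of the groups and without a clone name. Chance alone gives no overlap in 10% of all genes. Called genes were already chosen for a difference, so that share is no measure for this count.

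By cell type, luminal progenitor genes rose in 15 of 19 and fell in 1 (17 adjusted over the list alone, camera adjusted p = 1.1e-09, adjusted p = 0.277 with an estimated correlation). Prostate secretory genes fell in 13 of 26 and rose in 3 (20 adjusted over the list alone, camera adjusted p = 0.00125, adjusted p = 0.277 with an estimated correlation). Their median was −2.90, or −2.42 with undetected genes at their bound. Without wild-type 6, 15 of 26 secretory genes fell and 5 rose. Basal cell genes rose in 9 of 13 (9 adjusted over the list alone, camera adjusted p = 2.2e-05, adjusted p = 0.277 with an estimated correlation), with the keratin Krt15 up by 3.43 ± 0.58. Macrophage genes rose in 15 of 19 and fell in 1 (16 adjusted over the list alone, camera adjusted p = 2.9e-10, adjusted p = 0.277 with an estimated correlation), such as the chemokine receptor Cx3cr1 at 2.52 ± 0.27. Neutrophil genes rose in 8 of 15 (10 adjusted over the list alone, camera adjusted p = 1.5e-04, adjusted p = 0.345 with an estimated correlation), such as Padi4 at 3.83 ± 0.52. Lymphocyte genes rose in 16 of 22 (17 adjusted over the list alone, camera adjusted p = 1.1e-04, adjusted p = 0.433 with an estimated correlation), such as Cd5 at 3.29 ± 0.72. Of 22 lymphocyte genes 9 rose and 1 fell without Pten library 1, and 10 rose without wild-type 10.

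Smooth muscle genes fell in 11 of 14 (12 adjusted over the list alone, camera adjusted p = 5.4e-05, adjusted p = 0.277 with an estimated correlation), with the myosin Myh11 at −3.22 ± 0.69. Skeletal muscle genes fell in 11 of 17 (13 adjusted over the list alone, camera adjusted p = 0.00298, adjusted p = 0.433 with an estimated correlation). Endothelial genes rose in 10 of 15 (10 adjusted over the list alone, camera adjusted p = 0.00125, adjusted p = 0.433 with an estimated correlation) and fibroblast genes in 6 of 20 (6 adjusted over the list alone, camera adjusted p = 0.00289, adjusted p = 0.481 with an estimated correlation). Neuroendocrine genes rose in 7 of 15 (8 adjusted over the list alone, camera adjusted p = 0.00289, adjusted p = 0.393 with an estimated correlation), with the transcription factor Ascl1 up by 3.86 ± 0.79. All 10 seminal vesicle genes rose (10 adjusted over the list alone, median 13.19, camera adjusted p = 1.1e-07, adjusted p = 0.277 with an estimated correlation). Adipocyte genes (0 of 12), nerve genes (2 up and 2 down of 12) and erythroid genes (0 of 6) were not called as lists (camera adjusted p = 0.534, 0.549 and 0.878). Of these, 0, 5 and 0 were called when adjusted over the list alone. Single libraries moved several counts of this paragraph. Smooth muscle genes fell in 5 of 14 without Pten 1 or Pten 2 and in 6 without wild-type 6. Skeletal muscle genes fell in 2 of 17 and rose in 1 without wild-type 12 (median −0.40), and fell in 4, 6 and 5 of 18 without Pten 1, 2 and 3. Endothelial genes rose in 5 of 15 without wild-type 6 or Pten 2, and neuroendocrine genes in 3 of 15 without wild-type 12. Fibroblast genes rose in 1 of 20 without Pten 1, 2 without wild-type 12 and 3 without wild-type 6. Erythroid genes rose in 4 of 6 without Pten 3 (median 1.58), and 1 fell without wild-type 6 or Pten 1. Adipocyte genes fell in 3 of 12 without Pten 2 (median −2.64) and 1 without wild-type 6. Nerve genes rose in 0 of 12 without Pten 2, rose in 1 without wild-type 10, wild-type 12, Pten 1 or Pten 3, and fell in 1 without wild-type 6, Pten 1 or Pten 3.

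Among pathways, 28 of 41 senescence markers and secreted factors rose (28 adjusted over the list alone, camera adjusted p = 6.0e-12, adjusted p = 0.277 with an estimated correlation). They included Igfbp3, an insulin-like growth factor binding protein, at 3.09 ± 0.26 and the neutrophil chemokine Cxcl5 at 7.54 ± 0.84. Interferon-stimulated genes rose in 21 of 30 (22 adjusted over the list alone, camera adjusted p = 2.2e-10, adjusted p = 0.277 with an estimated correlation), with Oasl2 at 3.94 ± 0.47. Antigen presentation genes rose in 14 of 16 (14 adjusted over the list alone, camera adjusted p = 1.7e-07, adjusted p = 0.277 with an estimated correlation). Complement and acute phase genes rose in 9 of 17 and fell in 1 (11 adjusted over the list alone, camera adjusted p = 3.5e-05, adjusted p = 0.277 with an estimated correlation), with complement factor Cfb at 4.46 ± 0.63. Matrix metalloproteinases and their inhibitors rose in 16 of 25 and fell in 2 (18 adjusted over the list alone, camera adjusted p = 1.3e-04, adjusted p = 0.277 with an estimated correlation). Cell cycle genes rose in 16 of 31 (18 adjusted over the list alone, camera adjusted p = 1.5e-04, adjusted p = 0.481 with an estimated correlation). Glycolysis genes rose in 6 of 21 and fell in 1 (11 adjusted over the list alone, camera adjusted p = 7.3e-04, adjusted p = 0.433 with an estimated correlation). Immediate early genes rose in 7 of 20 (8 adjusted over the list alone, camera adjusted p = 0.0253, adjusted p = 0.481 with an estimated correlation). Of 31 cell cycle genes 1 rose without wild-type 10, wild-type 12 or Pten 1, 8 without Pten 2 and 25 without wild-type 6. Glycolysis genes rose in 12 of 21 without wild-type 6, and immediate early genes in 4 of 20 without Pten 1 (median 0.11).

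Unfolded protein response genes fell in 13 of 20 (13 adjusted over the list alone, camera adjusted p = 3.1e-07, adjusted p = 0.277 with an estimated correlation), with the endoplasmic reticulum co-chaperone Dnajc3 at −1.89 ± 0.27. That count was 8 without wild-type 6 (median −0.61) or Pten 1. Direct p53 targets rose in 8 of 29, among them the cell cycle inhibitor Cdkn1a at 2.10 ± 0.31, and fell in 4 (13 adjusted over the list alone). That list was not called (camera adjusted p = 0.227). Also not called were ATF4 targets (1 up and 6 down of 25, 4 adjusted over the list alone, camera adjusted p = 0.0903) and cholesterol synthesis (4 up and 1 down of 25, 3 adjusted over the list alone, camera adjusted p = 0.714). Neither was fatty acid synthesis (2 up of 19, 1 adjusted over the list alone, camera adjusted p = 0.962) or epithelial-mesenchymal transition (4 up of 18, 4 adjusted over the list alone, camera adjusted p = 0.0979). FOXO and PI3K targets (2 up and 6 down of 20, 8 adjusted over the list alone) were not called (camera adjusted p = 0.878), with a median of 0.11 and a mean of −0.05. Wnt and Notch genes (6 up and 2 down of 20, 8 adjusted over the list alone) were not called either (camera adjusted p = 0.0804), and 1 fell without wild-type 6, Pten 2 or Pten 3. ATF4 targets fell in 3 of 25 without wild-type 10, and none rose without wild-type 10, wild-type 12 or Pten 1. Cholesterol synthesis genes rose in 1 of 25 without Pten 1 and 2 without wild-type 10, where none fell, and 2 fell without wild-type 6. Fatty acid synthesis genes rose in 1 of 19 without wild-type 10, wild-type 12 or Pten 2 and in 4 without wild-type 6, with 3 falls without Pten 2 and 1 without wild-type 6. Epithelial-mesenchymal genes rose in 2 of 18 without Pten 2. FOXO and PI3K targets fell in 3 of 20 without wild-type 12 or Pten 2 and rose in 5 without wild-type 6.

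Genes of the translation machinery fell together. Of 78 ribosomal protein genes 77 fell (77 adjusted over the list alone, median −2.27, camera adjusted p = 2.3e-19, adjusted p = 0.393 with an estimated correlation), with Rpl10 at −3.26 ± 0.59. This fall depended on wild-type library 10, in which these genes took 8.14% of counts, against 3.20% and 1.18% in the other wild-type libraries and 1.13 to 1.54% in Pten. Without it 34 of 78 fell, with a median of −1.06. Without it 9 of 27 translation factors, 2 of 14 host genes of small nucleolar RNAs, 1 of 10 mitochondrially encoded genes, 1 of 12 small structural RNAs and 0 of 45 respiratory chain genes fell. Mitochondrially encoded genes fell in 1 of 11 without Pten 1 or Pten 2 as well, host genes in 3 and 4 of 14 without Pten 2 and Pten 3, and small structural RNAs in 3, 2 and 3 of 12 without Pten 1, 2 and 3. Respiratory chain genes fell in 0 of 45 without Pten 1 or Pten 2, 1 without Pten 3 and 5 without wild-type 6. Small structural RNAs took 0.652, 0.168 and 0.0307% of counts in wild-type libraries 10, 12 and 6, and mitochondrially encoded genes 1.60, 0.697 and 0.523%. Translation factors fell in 20 of 27 (21 adjusted over the list alone, camera adjusted p = 5.1e-08, adjusted p = 0.277 with an estimated correlation), with the eIF4E-binding protein Eif4ebp1 at −3.05 ± 0.54. Host genes of small nucleolar RNAs fell in 9 of 14 (12 adjusted over the list alone, camera adjusted p = 2.9e-04, adjusted p = 0.433 with an estimated correlation). Mitochondrially encoded genes fell in 6 of 10 (7 adjusted over the list alone, camera adjusted p = 0.00125, adjusted p = 0.433 with an estimated correlation) and small structural RNAs in 6 of 12 (6 adjusted over the list alone, camera adjusted p = 0.0272, adjusted p = 0.487 with an estimated correlation). Nuclear-encoded respiratory chain genes fell in 2 of 45 (0 adjusted over the list alone, camera adjusted p = 0.00878, adjusted p = 0.671 with an estimated correlation). Nuclear long noncoding RNAs (2 of 10 fell, 2 adjusted over the list alone) were not called (camera adjusted p = 0.109). Histones (1 up and 1 down of 23, 2 adjusted over the list alone) were not called (camera adjusted p = 0.962), with a median of −0.15 and a mean of 0.08. Without wild-type 6, 2 histones rose and 3 fell, and none fell without wild-type 10, wild-type 12, Pten 1 or Pten 2. In every comparison without a mouse term, each list that camera called had a median, a mean and a test of the same sign.

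None of the 27 list calls in Pten against wild type held when the correlation between genes was estimated. As a fact of composition, the secreted spermine-binding protein Sbp took 12.6% and 10.9% of counts in wild-type libraries 10 and 12. The gene 9530053A07Rik took 28.5% in wild-type library 6, and seminal vesicle genes took 7.38 to 10.7% in Pten. With only the groups compared in the fit, 2777 genes were called and the gene Pten did not pass (adjusted p = 0.0518, against 0.00126 to 0.0518 over all alternatives for Pten in Pten vs WT).

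**Figure D2:**
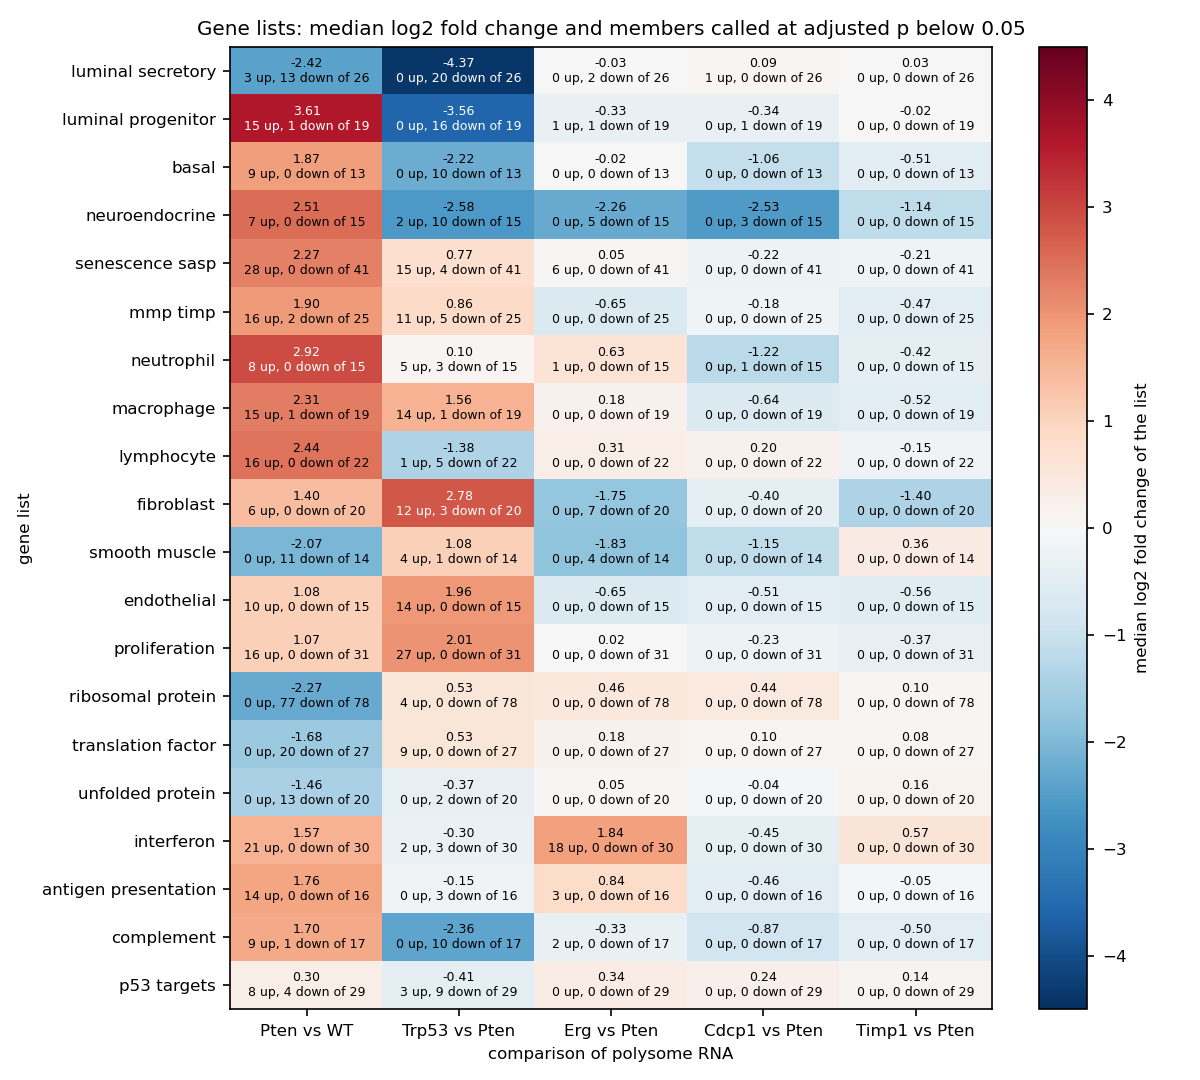
Median log2 fold change (colour, with undetected genes at their bound) of 20 gene lists (vertical axis) in the 5 comparisons of polysome-bound RNA (horizontal axis), with the number of members that rose and fell of those tested written in each cell. Ribosomal protein genes show 77 falls of 78 in Pten against wild type, and interferon-stimulated genes 18 rises of 30 in Erg against Pten.

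In Trp53 against Pten, most luminal and basal epithelial genes listed fell and most cell cycle, endothelial and fibroblast genes rose in polysome-bound RNA. The luminal keratins Krt8 (chromosome 15, 101996698 to 102004482) and Krt18 changed by −3.48 ± 0.38 (adjusted p = 1.2e-05) and −3.31 ± 0.40. The epithelial splicing regulators Esrp1 (chromosome 4, 11331933 to 11386783) and Esrp2 changed by −3.91 ± 0.41 (adjusted p = 1.0e-05) and −3.41 ± 0.30 (adjusted p = 5.9e-06). The chromatin protein Hmga2 (chromosome 10, 120361275 to 120476469) rose by 6.64 ± 0.95 (adjusted p = 8.3e-05), and the imprinted long noncoding RNA Meg3 (chromosome 12, 109541001 to 109571726) by 6.65 ± 0.96. The growth factor Ptn (chromosome 6, 36714929 to 36810220) rose by 6.48 ± 0.96. The transcription factors Tbx15 (chromosome 3, 99240381 to 99354259) and Shox2 (chromosome 3, 66971727 to 66981771) rose by 6.73 ± 1.31 and 6.47 ± 1.12. Cdkn2a, the locus of a cell cycle inhibitor (chromosome 4, 89274471 to 89294653), rose by 3.89 ± 0.63 (adjusted p = 2.3e-04), from 16.4 ± 2.48 to 244 ± 41.2 normalised CPM (SD). In the other direction Svs6 changed by −13.80 ± 2.32 and Sbp (chromosome 17, 23941672 to 23945607) by −13.31 ± 2.38, and Pbsn was at least 1028-fold lower. A total of 7675 genes were called, 3786 up and 3889 down, of which 5608 were abundant, free of overlap and without a clone name.

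Secretory genes fell in 20 of 26 in Trp53 against Pten (21 adjusted over the list alone, camera adjusted p = 4.1e-08), and luminal progenitor genes in 16 of 19 (16 adjusted over the list alone, camera adjusted p = 2.0e-07). Both had adjusted p = 0.465 with an estimated correlation. Basal genes fell in 10 of 13 (12 adjusted over the list alone, camera adjusted p = 1.7e-06, adjusted p = 0.486 with an estimated correlation). Examples were Psca, a prostate stem cell antigen, at −7.96 ± 1.17 and the basal factor Trp63 at −3.16 ± 0.47. Cell cycle genes rose in 27 of 31 (29 adjusted over the list alone, camera adjusted p = 2.2e-11, adjusted p = 0.508 with an estimated correlation). Among them the mitotic transcription factor Foxm1 rose by 2.76 ± 0.32. Histones rose in 12 of 23 (12 adjusted over the list alone, camera adjusted p = 0.00202, adjusted p = 0.65 with an estimated correlation). Endothelial genes rose in 14 of 15 (14 adjusted over the list alone, camera adjusted p = 6.4e-07, adjusted p = 0.486 with an estimated correlation), such as Pecam1 at 2.10 ± 0.33. Macrophage genes rose in 14 of 19 and fell in 1 (16 adjusted over the list alone, camera adjusted p = 3.2e-05, adjusted p = 0.508 with an estimated correlation), such as Cx3cr1 at 2.90 ± 0.27. Fibroblast genes rose in 12 of 20 and fell in 3 (15 adjusted over the list alone, camera adjusted p = 0.00598, adjusted p = 0.65 with an estimated correlation), such as Pdgfra at 2.79 ± 0.43. Senescence and secreted factors rose in 15 of 41 and fell in 4 (20 adjusted over the list alone, camera adjusted p = 0.0261, adjusted p = 0.65 with an estimated correlation). The monocyte chemokine Ccl2 rose by 4.43 ± 0.71. Direct p53 targets fell in 9 of 29 and rose in 3 (12 adjusted over the list alone, median −0.41), with Trp53inp1 at −2.10 ± 0.31. Camera did not call the p53 list (adjusted p = 0.108), while fry did (adjusted p = 0.00483). All 18 genes of the epithelial-mesenchymal list were called, 9 up and 9 down (18 adjusted over the list alone), and camera did not call the list (adjusted p = 0.236).

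Metabolic and secreted-protein lists moved as well in Trp53 against Pten. Fatty acid synthesis genes fell in 9 of 19 and rose in 1 (13 adjusted over the list alone, camera adjusted p = 0.00398, adjusted p = 0.508 with an estimated correlation). Acss2, which makes acetyl-CoA from acetate, changed by −2.73 ± 0.33 and the lipogenic factor Srebf1 by −1.74 ± 0.35. Complement and acute phase genes fell in 10 of 17 (11 adjusted over the list alone, camera adjusted p = 6.2e-04, adjusted p = 0.508 with an estimated correlation). The polymeric immunoglobulin receptor Pigr changed by −4.85 ± 0.76. ATF4 targets rose in 11 of 25 and fell in 2 (14 adjusted over the list alone, camera adjusted p = 0.0133, adjusted p = 0.508 with an estimated correlation). Immediate early genes (3 up and 2 down of 20, 5 adjusted over the list alone) were not called (camera adjusted p = 0.536), with a median of −0.11 and a mean of 0.22. Of that list, the AP-1 gene Fosl1 rose by 4.71 ± 0.67 and Myc by 1.60 ± 0.29. Adipocyte genes fell in 11 of 12 (11 adjusted over the list alone, camera adjusted p = 3.7e-04, adjusted p = 0.638 with an estimated correlation). Their levels varied widely between Pten libraries, such as 40.1 ± 55.4 normalised CPM (SD) for the lipid droplet gene Plin1. Seminal vesicle genes fell in 9 of 10 (10 adjusted over the list alone, camera adjusted p = 1.7e-05, adjusted p = 0.508 with an estimated correlation). They took 0.001 to 0.227% of counts in Trp53 and 7.38 to 10.7% in Pten.

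In Erg against Pten, most interferon-stimulated genes rose and most seminal vesicle genes fell in polysome-bound RNA. Of 30 interferon-stimulated genes 18 rose (28 adjusted over the list alone, median 1.84, camera adjusted p = 9.5e-29, adjusted p = 0.163 with an estimated correlation). The antiviral tetherin Bst2 (chromosome 8, 71534255 to 71537456) rose by 1.82 ± 0.32 (adjusted p = 0.00641). The signal transducers Stat1 (chromosome 1, 52119440 to 52161865) and Stat2 rose by 2.05 ± 0.38 (adjusted p = 0.00744) and 1.74 ± 0.31. Antigen presentation genes rose in 3 of 16 (7 adjusted over the list alone, camera adjusted p = 6.6e-06, adjusted p = 0.383 with an estimated correlation). Of these the peptide transporter Tap1 (chromosome 17, 34187553 to 34197225) rose by 1.91 ± 0.31 (adjusted p = 0.00392). The acute phase gene Saa3 (chromosome 7, 46711998 to 46715700) rose by 4.68 ± 0.58 (adjusted p = 8.7e-04). The mucin Muc3 (chromosome 5, 137134922 to 137149322) rose by 6.43 ± 1.04 and the lipase Lipm (chromosome 19, 34100933 to 34122687) by 6.27 ± 1.13. Otos (chromosome 1, 92644218 to 92648841) rose by 8.15 ± 0.83 and Otol1 (chromosome 3, 70007613 to 70028708) at least 472-fold. The serotonin synthesis gene Tph1 fell by 4.34 ± 0.73 (adjusted p = 0.00457), and the secreted Wnt inhibitor Notum fell by 3.73 ± 0.60 (adjusted p = 0.00389). The lipoprotein receptor Vldlr fell by 1.90 ± 0.31. Seminal vesicle genes fell in 9 of 10 (9 adjusted over the list alone, camera adjusted p = 4.3e-15, adjusted p = 0.163 with an estimated correlation). Svs6 changed by −14.54 ± 2.42 and Svs3b (chromosome 2, 164254363 to 164256640) by −13.80 ± 2.30.

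Fibroblast genes fell in 7 of 20 in Erg against Pten (15 adjusted over the list alone, camera adjusted p = 3.2e-09, adjusted p = 0.383 with an estimated correlation). Smooth muscle genes fell in 4 of 14 (10 adjusted over the list alone, camera adjusted p = 2.6e-06, adjusted p = 0.358 with an estimated correlation). Neuroendocrine genes fell in 5 of 15 (11 adjusted over the list alone, camera adjusted p = 6.1e-09, adjusted p = 0.163 with an estimated correlation). Erythroid genes fell in 4 of 6 (5 adjusted over the list alone, camera adjusted p = 3.9e-04, adjusted p = 0.428 with an estimated correlation). No ribosomal protein gene of 78 was called (0 adjusted over the list alone, median 0.46), although camera called the list (adjusted p = 1.3e-04, adjusted p = 0.878 with an estimated correlation). Basal genes (0 of 13, 1 adjusted over the list alone, median −0.02, mean 0.04) and cell cycle genes (0 of 31, median 0.02, mean −0.02) were not called as lists. The 1032 calls, 332 up and 700 down, moved with single libraries. There were 118 without Erg library 1, 127 without Erg 3, 498 without Erg 4, 322 without Pten 2 and 674 without Pten 3. Of 68 named genes 21 kept their call with every library left out in turn, and each single gene named above for this comparison is one of those. Mitochondrial ribosomal RNA took 9.31 to 10.3% of counts in Erg polysome libraries and 0.719 to 1.29% in Pten. The ribosomal RNA gene Gm23935 took 6.15 to 6.99% and 0.342 to 0.587%. Totals were 16927945 to 20853470 counts in Erg and 28320297 to 33778108 in Pten.

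Between the libraries labelled Cdcp1 and Pten, 120 genes of polysome-bound RNA were called. The arylacetamide deacetylase-like gene Aadacl3 (chromosome 4, 144453771 to 144463756) rose by 7.86 ± 0.86 (adjusted p = 4.1e-04), from 0.0584 ± 0.0535 to 14.2 ± 2.34 normalised CPM (SD). The enolase copy Eno1b (chromosome 18, 48045335 to 48048412) rose by 5.77 ± 0.60 (adjusted p = 3.4e-04). These were the 2 of 24 named genes that kept their call with every library left out in turn. Calls were 48 up and 72 down, or 40.0% up, against 50.5% up with upper quartile scaling, and DESeq2 called 1134. The count was 64 without Pten library 1, 14 without Pten 2 and 754 without library 3 labelled Cdcp1 (392 up and 362 down). Without Pten 3 it was 128, with 24 up and 104 down. The balance turned to 20 up and 9 down without library 2 labelled Cdcp1 and to 12 up and 1 down without library 1. Neuroendocrine genes fell in 3 of 15 (10 adjusted over the list alone, camera adjusted p = 8.2e-10, adjusted p = 0.315 with an estimated correlation, fry adjusted p = 0.0156). Adipocyte genes fell in 1 of 12 (12 adjusted over the list alone, camera adjusted p = 4.4e-07, adjusted p = 0.515 with an estimated correlation). Basal genes had 0 of 13 called (5 adjusted over the list alone), with a median of −1.06 (camera adjusted p = 1.5e-04, adjusted p = 0.515 with an estimated correlation). Smooth muscle genes had 0 of 14 called (6 adjusted over the list alone), with a median of −1.15 (camera adjusted p = 4.8e-06, adjusted p = 0.515 with an estimated correlation). The 3 libraries labelled Cdcp1 were unlike each other. Seminal vesicle genes took 0.0439, 0.141 and 13.9% of counts in mice 1, 2 and 3, and mitochondrial ribosomal RNA took 4.34, 22.5 and 0.990%.

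Timp1 and Pten differed in 0 genes of polysome-bound RNA by edgeR's quasi-likelihood test (smallest adjusted p = 0.137, 1258 genes at an unadjusted p under 0.05), while DESeq2 called 29. In each list named here 0 genes were called, and 0 adjusted over the list alone. Fibroblast genes lay lower in Timp1, with a median of −1.40 (camera adjusted p = 4.4e-11). Endothelial genes had a median of −0.56 (camera adjusted p = 3.5e-05) and neuroendocrine genes of −1.14 (camera adjusted p = 3.7e-05). Interferon-stimulated genes lay higher, with a median of 0.57 (camera adjusted p = 8.0e-05), as did mitochondrially encoded genes at 1.70 (camera adjusted p = 3.5e-06) and skeletal muscle genes at 1.26 (camera adjusted p = 1.1e-04). None of the 13 list calls held, since the smallest over the 39 lists was adjusted p = 0.748 with an estimated correlation. Seminal vesicle genes took 17.3 to 22.6% of counts in the Timp1 polysome libraries.

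**Figure D3:**
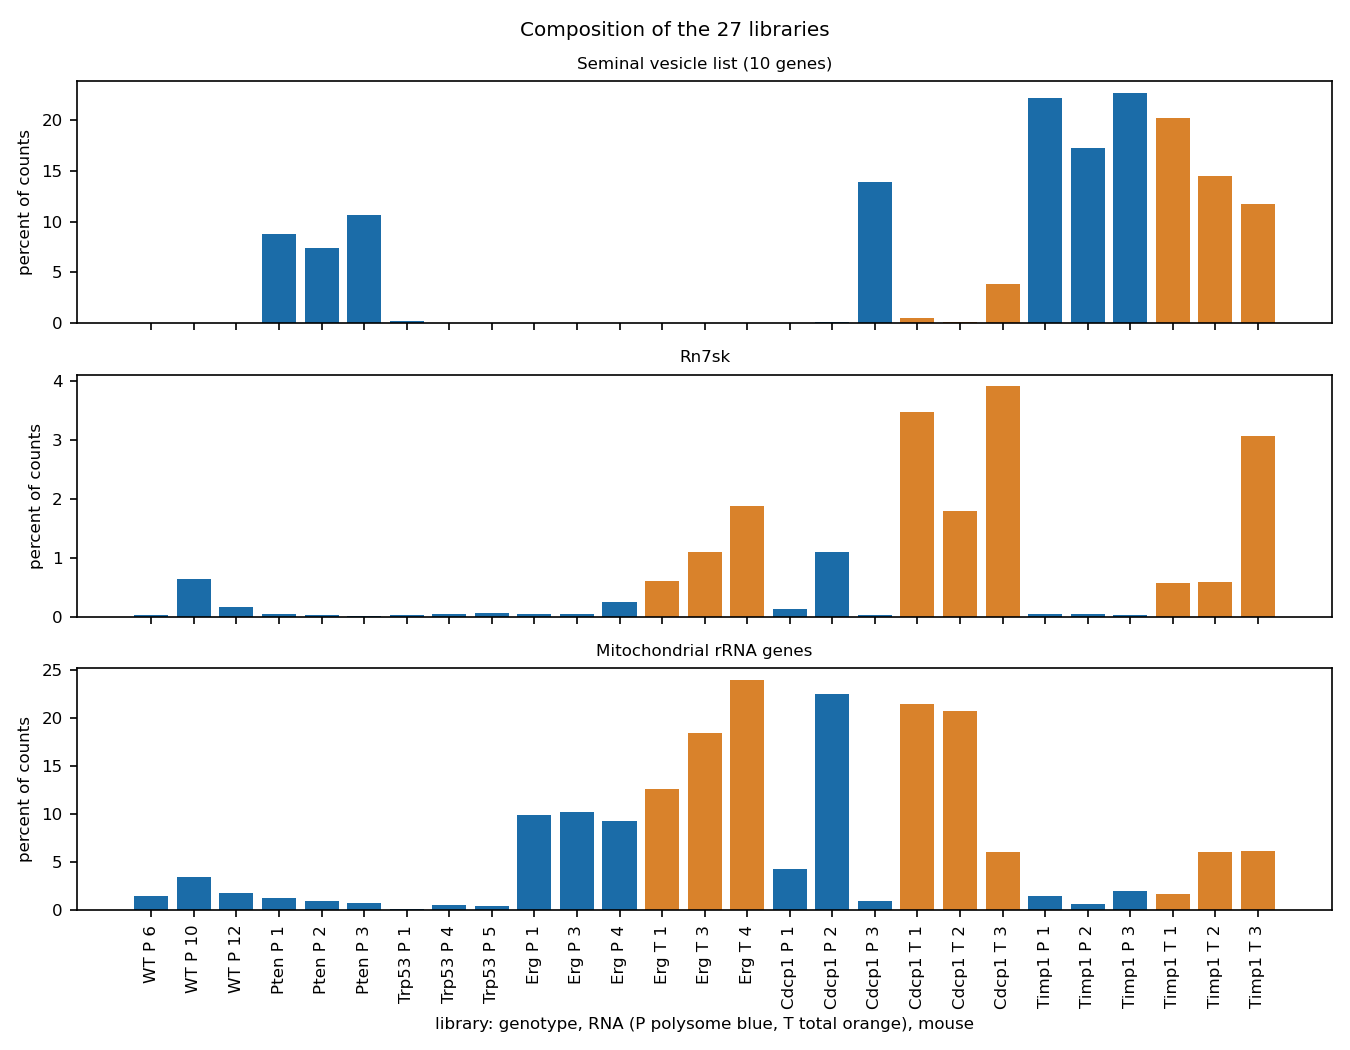
Share of counts (percent, vertical axes) taken by the seminal vesicle list, by the small nuclear RNA Rn7sk and by mitochondrial ribosomal RNA in each of the 27 libraries, 1 bar per library and 1 panel per class. Seminal vesicle genes reach 22.6% in Timp1 polysome library 3 and are near 0 in wild type and Erg, and mitochondrial ribosomal RNA reaches 24.0% in Erg total library 4.

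Total RNA was compared between the genotypes for which it was sequenced. The Erg libraries stood apart in totals (13352451 to 15593968 counts, against 20667198 to 47267257 in the others) and in Gm23935 (6.85 to 11.5% of counts, against 0.154 to 0.854%). Mitochondrial ribosomal RNA took 12.6 to 24.0% in Erg, 6.02 to 21.5% in the libraries labelled Cdcp1 and 1.74 to 6.15% in Timp1. Seminal vesicle genes took 0.00145 to 0.00152% in Erg, 0.186 to 3.84% in the libraries labelled Cdcp1 and 11.7 to 20.1% in Timp1. Interferon-stimulated genes fell in 27 of 30 in the libraries labelled Cdcp1 against Erg (27 adjusted over the list alone, median −2.06, camera adjusted p = 3.3e-28, adjusted p = 0.23 with an estimated correlation). They fell in 22 of 30 in Timp1 against Erg (28 adjusted over the list alone, median −1.26, camera adjusted p = 2.1e-17, adjusted p = 0.308 with an estimated correlation). Tap1 changed by −2.75 ± 0.31 (adjusted p = 4.0e-05) and −1.83 ± 0.30 (adjusted p = 0.00101) in these comparisons. Saa3 changed by −7.22 ± 0.47 (adjusted p = 3.3e-07) and −3.87 ± 0.38 (adjusted p = 1.5e-05), the collagenase Mmp13 by −4.04 ± 0.41 and −4.90 ± 0.43, and Otos by −7.86 ± 0.61 and −8.30 ± 0.62. Antigen presentation genes fell in 13 of 16 and 8 of 16 (13 and 10 adjusted over the list alone, camera adjusted p = 6.5e-10 and 1.9e-07). They had adjusted p = 0.23 and 0.308 with an estimated correlation. In the libraries labelled Cdcp1, 18 of 23 histone genes fell against Erg (21 adjusted over the list alone, camera adjusted p = 4.5e-09, adjusted p = 0.607 with an estimated correlation). Neutrophil genes fell there in 10 of 11 (10 adjusted over the list alone, camera adjusted p = 1.5e-07, adjusted p = 0.23 with an estimated correlation). Respiratory chain genes fell in 18 of 45 (22 adjusted over the list alone, camera adjusted p = 6.2e-07, adjusted p = 0.658 with an estimated correlation). The nuclear RNA Malat1 rose by 4.41 ± 1.06 (adjusted p = 0.0067). In Timp1 against Erg, 10 of 14 smooth muscle genes rose (12 adjusted over the list alone, camera adjusted p = 6.1e-08, adjusted p = 0.308 with an estimated correlation), with Myh11 at 3.27 ± 0.49. Skeletal muscle genes rose in 12 of 16 (15 adjusted over the list alone, camera adjusted p = 6.6e-09, adjusted p = 0.308 with an estimated correlation). The fatty acid elongase Elovl6 (chromosome 3, 129532355 to 129638495) rose by 2.64 ± 0.28 (adjusted p = 3.0e-05).

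The libraries labelled Cdcp1 differed from Erg in 6211 of 17957 genes in total RNA, 3349 up and 2862 down. The count was 3421 without Erg library 1 (1621 up and 1800 down) and 4034 without Erg 3 (1940 up and 2094 down), so that the balance turned, and upper quartile scaling moved the median of all genes by 0.13. Timp1 differed from Erg in 2609 genes, 1365 up and 1244 down. The count was 1326 without Erg 1, 1421 without Erg 3, 1506 without Timp1 2 and 1637 without Timp1 3, and without Erg 4 the balance turned to 900 up and 947 down. Timp1 differed from the libraries labelled Cdcp1 in 780 genes, 496 up and 284 down, and in 1324 with the replicate number as a block. The count was 243 without Timp1 2, 125 without Timp1 1 and 129 without library 1 labelled Cdcp1. Without library 2 labelled Cdcp1 the balance turned to 302 up and 451 down. Adipocyte genes rose in 11 of 12 in this last comparison (11 adjusted over the list alone, median 2.90, camera adjusted p = 2.5e-15, adjusted p = 0.138 with an estimated correlation). The fatty acid binding protein Fabp4 (chromosome 3, 10204088 to 10208576) rose by 3.29 ± 0.51 (adjusted p = 0.00311) and the lipogenic gene Thrsp (chromosome 7, 97412938 to 97417730) by 3.26 ± 0.33 (adjusted p = 8.7e-05). Interferon-stimulated genes rose in 11 of 30 (18 adjusted over the list alone, camera adjusted p = 1.6e-10, adjusted p = 0.413 with an estimated correlation), with Bst2 at 1.86 ± 0.33. Aadacl3 and Eno1b changed by −7.73 ± 0.68 and −6.48 ± 0.55 (adjusted p = 2.0e-05 each). Timp1 itself fell by 3.13 ± 0.73 (adjusted p = 0.0269), a call that ended without Timp1 library 2 (0.103), Timp1 1 (0.143), or libraries 3 (0.0707) or 1 (0.0799) labelled Cdcp1. For Timp1 in Timp1 vs Cdcp1 total the adjusted p ran from 1.1e-04 to 0.143 over all alternatives. Adipocyte and skeletal muscle markers, which are not of the prostate epithelium, differed between the groups in these comparisons. An effect of the genotype and a difference in the tissue taken were not told apart.

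Polysome-bound RNA was compared with total RNA of the same mice to ask which transcripts were carried by ribosomes. Values are given in the order Erg, Cdcp1 and Timp1. Small structural RNAs, which are not translated, lay lower in polysomes, with medians of −3.00, −2.96 and −2.72. Of 13 such genes 12, 10 and 8 were called when adjusted over the list alone (camera adjusted p = 4.1e-43, 4.2e-18 and 4.5e-17). They had adjusted p = 0.00826, 0.183 and 0.268 with an estimated correlation. Ribosomal protein transcripts lay lower too, with medians of −1.06, −1.05 and −0.99. Of 78 genes 53, 51 and 43 were called when adjusted over the list alone (camera adjusted p = 4.2e-97, 1.3e-32 and 2.1e-57). These lists had adjusted p = 0.0847, 0.611 and 0.399 with an estimated correlation. Respiratory chain genes lay higher, with medians of 0.17, 0.88 and 0.30. Of 45 genes 0, 30 and 0 were called when adjusted over the list alone (camera adjusted p = 0.0363, 9.6e-19 and 2.7e-07). The same test gave adjusted p = 0.917, 0.611 and 0.829 with an estimated correlation. Histones lay higher at 0.28, 1.05 and 0.42, with 0, 6 and 0 of 23 adjusted over the list alone (camera adjusted p = 0.00215, 6.6e-08 and 1.3e-05). For histones too it gave adjusted p = 0.917, 0.611 and 0.829 with an estimated correlation. Interferon-stimulated genes did not pass, with medians of 0.02, −0.08 and −0.04. Over all genes edgeR's quasi-likelihood test called 0 in each group, with 380, 2758 and 460 genes at an unadjusted p under 0.05, and DESeq2 called 6, 18 and 10. With the mouse as a block it called 0 too, with 665, 5231 and 1265 at an unadjusted p under 0.05. In that fit the small structural RNAs in Erg had adjusted p = 0.0656 with an estimated correlation.

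The polysome library of mouse 2 labelled Cdcp1 stood apart. Its median ratio to total RNA was −1.04 for small structural RNAs and −0.02 for ribosomal protein genes, against −4.83 to −1.45 and −2.02 to −0.29 in the other 8 mice. Respiratory chain genes and histones had medians of −0.29 and −0.37 there, and of 0.10 to 1.36 and 0.17 to 2.01 in the other 8 mice. Without that library alone, 4677 genes were called in the libraries labelled Cdcp1. Without both libraries of that mouse and with the mouse as a block, 7267 genes were called in Cdcp1 polysome vs total, 3520 up and 3747 down. Ribosomal protein genes fell in 71 of 79 and translation factors in 18 of 27, with 4 rises, while 41 of 45 respiratory chain and 20 of 23 histone genes rose. The poly(A)-binding protein gene Pabpc1 changed by −3.04 ± 0.38, the elongation factor gene Eef1a1 by −2.42, and the small RNA Rn7sk by −6.07 ± 0.84. Cox7a1 of the respiratory chain rose by 2.13 and the histone gene Hist1h4a by 2.09 ± 0.25. Markers of other tissues differed between the libraries of a mouse too. In mice 1 and 3 labelled Cdcp1, seminal vesicle genes had median ratios of −3.94 and 1.93, and smooth muscle genes of −0.61 and −1.08. Whether the polysome and total RNA libraries of a mouse held the same tissue was not tested. With the mouse as a block and the libraries of 1 genotype alone, 1587 genes were called in Erg polysome vs total, 619 up and 968 down. The same fit called 1385 in Timp1 polysome vs total, 362 up and 1023 down. Ribosomal protein genes fell in 49 of 78 in Erg, with Rpl37a at −1.62 ± 0.07 (adjusted p = 1.3e-22), and in 42 of 78 in Timp1. Fth1, the ferritin heavy chain under translational control by iron, changed by −2.10 ± 0.14 in Timp1 (adjusted p = 1.4e-19) and the light chain Ftl1 by −1.77 ± 0.14. These fits were chosen after seeing the data. Errors and p-values of the fits within 1 genotype may understate the spread between the 3 mice. Median ratios of ribosomal protein genes were −0.78, −1.39 and −0.91 in Erg mice 1, 3 and 4. They were −0.29, −0.96 and −1.45 in Timp1 mice 1, 2 and 3.

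**Figure D4:**
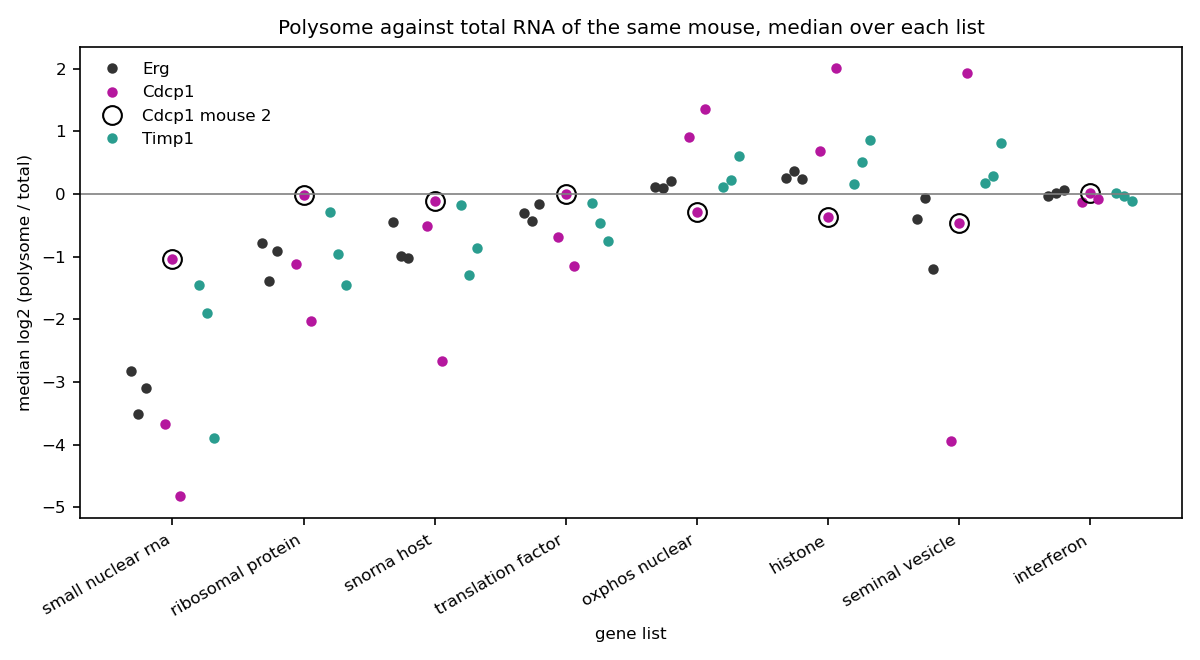
Median log2 ratio of polysome to total RNA (vertical axis) of 8 gene lists (horizontal axis), 1 point per mouse and 9 mice of the Erg, Cdcp1 and Timp1 groups, with mouse 2 labelled Cdcp1 circled. Small structural RNAs lie between −4.83 and −1.45 in 8 mice and at −1.04 in the circled mouse.

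Differences between genotypes in the ratio of polysome to total RNA were tested as an interaction. EdgeR's quasi-likelihood test called 0 genes for Cdcp1 against Erg, Timp1 against Erg and Timp1 against Cdcp1, with 214, 54 and 70 genes at an unadjusted p under 0.05. DESeq2 called 0, with 277, 86 and 141 at that level. Respiratory chain genes lay higher in this ratio in the libraries labelled Cdcp1 than in Erg, with a median of 0.79 (0 of 45 adjusted over the list alone, camera adjusted p = 4.4e-19, adjusted p = 0.851 with an estimated correlation). Histones lay higher too, with a median of 0.81 (0 of 23 adjusted over the list alone, camera adjusted p = 5.5e-05, adjusted p = 0.851 with an estimated correlation). The mice labelled Cdcp1 did not move together: mouse 2 had medians of −0.29 for the respiratory chain (42 of 45 genes below 0) and −0.37 for histones (23 of 23). Mice 1 and 3 had 0.91 and 1.36, and 0.69 and 2.01. Timp1 lay below Cdcp1 for both, with medians of −0.55 and −0.73 (camera adjusted p = 2.1e-14 and 4.6e-04). Here the lists had adjusted p = 0.862 and 0.979 with an estimated correlation. Timp1 and Erg differed by 0.15 for the respiratory chain (camera adjusted p = 0.0173, adjusted p = 0.925 with an estimated correlation). With the mouse as a block, 0 genes were called in each, with 609, 182 and 330 at an unadjusted p under 0.05, and 9 lists instead of 3 for Timp1 against Erg.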

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

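The list tests of the polysome-to-total ratio without a mouse term were fixed before the data were examined. All other tests in this part were chosen after the results they weigh were seen. The first test on seminal vesicle genes was replaced after its outcome was known.

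Differences between genotypes in the ratio of polysome to total RNA, measured by a test of the difference itself, stood out in 5 results. In the libraries labelled Cdcp1 against Erg, 10 gene lists differed in that ratio by camera. Among them were respiratory chain genes, histones, translation factors and smooth muscle genes, and the smallest was adjusted p = 0.851 with an estimated correlation. In Timp1 against Erg 3 lists differed, namely seminal vesicle genes (median 0.85, at 0.00145 to 0.00182% of counts in the Erg libraries and so near the floor), respiratory chain genes (0.15) and small structural RNAs (0.30), with adjusted p = 0.925 or above with an estimated correlation. In Timp1 against the libraries labelled Cdcp1 12 lists differed, among them respiratory chain genes (−0.55), histones (−0.73) and small structural RNAs (0.24), with adjusted p = 0.568 or above with an estimated correlation. With the mouse as a block and both libraries of mouse 2 labelled Cdcp1 left out, 950 genes differed in Cdcp1 vs Erg translation, 585 up and 365 down, with 2 mice against 3. The respiratory chain gene Cox8a was at 1.40 ± 0.22, the histone gene Hist1h4c at 1.53 ± 0.26 and Pabpc1 at −2.22 ± 0.46 (adjusted p = 0.0223, 0.0223 and 0.0323). In the same fit 16 genes differed in Timp1 vs Cdcp1 translation, 14 up and 2 down. The small Cajal body RNA Scarna2 was at 2.36 ± 0.29 (adjusted p = 0.0169), the muscle filament gene Des at 1.82 ± 0.24 and the mitochondrial gene Fam162a at −1.12 ± 0.18. Of the mice labelled Cdcp1 this fit keeps 1 and 3. There seminal vesicle genes took 0.0439 and 13.9% of counts in polysomes, and 0.501 and 3.84% in total RNA. Different tissue in the libraries of a mouse and a change of translation were not told apart.

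Seminal vesicle transcripts took from under 0.01 to 22.6% of counts. RNA of seminal vesicle tissue of fixed composition in every library is excluded, since the members' ratios varied by an SD of 1.33 over the 10 polysome libraries with such counts. Over the 7 with the most the SD was 0.398, so in those such tissue stays open. The genotype alone is excluded as well, because the share differed 317-fold among the 3 polysome libraries labelled Cdcp1. Displacement of other genes by these counts did not set the calls between Pten and wild type through the scaling. Calls numbered 6044 without the list and its 50 closest correlates and 6128 with them. TMM scaling already limits the weight of such genes, so little change was likely from the start. Expression of these genes by tumour cells of some mice was not tested.

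The polysome library of mouse 2 labelled Cdcp1 lay close to its own total RNA. A library of another mouse is excluded, since its chi-square per degree of freedom was 107 with the closest library of any other mouse and 14.4 with the mouse's own total RNA. A change of translation alone is excluded, since Rn7sk, which is not translated, had a polysome to total ratio of 0.615 there and 0.00793 to 0.139 in the other 8 mice. Total RNA in place of, or carried into, the polysome fraction stays open: this ratio and the medians of respiratory chain genes (−0.29) and histones (−0.37) lay outside the range of the other mice, near or past 0, but small structural RNAs, at −1.04 against −4.83 to −1.45 in the other mice, missed the bound of −1 set for that test. No other biological explanation for this 1 mouse was tested.

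Ribosomal protein transcripts fell in Pten against wild type, with a median of −2.27. Gene length, GC content and abundance are excluded as the whole cause, since 10000 lists of other genes matched for them had a median of −0.24 and ran from −0.86 to 0.48. A few abundant genes taking most of the counts did not set the fall through the scaling of the libraries. Without 215 abundant and secretory genes the median was −2.22 and 77 of 78 genes fell. TMM scaling already limits the weight of such genes, so little change was likely from the start and this test excludes nothing more. Wild-type library 10 alone is excluded as the whole cause but carried much of the size, since without it the median was −1.06, a value close to the bound of −1 set for that test, and 34 of 78 genes fell. The loss of Pten, a difference in the lobes or cells sampled from wild-type mice, and total RNA carried into wild-type library 10 stay open. None of these was tested. Rn7sk took 0.642% of counts in wild-type library 10, and 0.161 and 0.0284% in wild-type 12 and 6. It took 0.577 to 3.90% in the total RNA libraries of the other genotypes.

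With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called most genes, 1 of 10, in Pten against wild type (6128, highest other 24), Trp53 against Pten (7675, 0), Erg against Pten (1032, 0) and Cdcp1 against Pten (120, 0). It also did in total RNA of Cdcp1 against Erg (6211, 0), Timp1 against Erg (2609, 0) and Timp1 against Cdcp1 (780, 0). Where the real split called 0 genes, all 10 of 10 splits reach that count by construction, so this decides nothing for Timp1 against Pten, polysome against total RNA in the 3 groups and the 3 translation comparisons. In polysome against total RNA of the libraries labelled Cdcp1, another split called 4289 genes, which points to a structure of the samples, and splits that part all 3 pairs called 0.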

How the results depend on the processing

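Settings that left out both libraries of mouse 2 labelled Cdcp1, fitted 1 genotype alone, used the mouse as a block in the list tests of translation and of polysome against total RNA, or removed the seminal vesicle genes were chosen after seeing the data, and all other settings before. The cause was not tested unless fewer genes or libraries are named. With each library left out in turn, the named genes that kept their call were 120 of 152 in Pten against wild type, 128 of 156 in Trp53 against Pten, 21 of 68 in Erg against Pten and 2 of 24 in Cdcp1 against Pten. In total RNA they were 102 of 150 for Cdcp1 against Erg, 80 of 109 for Timp1 against Erg and 14 of 71 for Timp1 against Cdcp1. Calls in Pten against wild type stayed within 1.5 times of 6128 under each setting, such as 7409 with all 27 libraries and 6336 without a filter (5009 shared), except with only the groups compared, 2777. Without a filter, with all 27 libraries, with DESeq2 and with only the groups compared, Erg against Pten had 2453, 1943, 2041 and 3533 calls, Cdcp1 against Pten 1730, 870, 1134 and 17, and Timp1 against Pten 402, 3, 29 and 1. For Timp1 in Timp1 vs Pten the first 3 of these settings gave adjusted p = 1.5e-27, 0.0242 and 2.5e-08. DESeq2 called 6, 18 and 10 genes for polysome against total RNA in Erg, Cdcp1 and Timp1, and the fit of only the groups compared called 2 in Erg. In total RNA all 27 libraries in 1 fit gave 1146 for Timp1 against Erg and 97 for Timp1 against Cdcp1, where DESeq2 gave 2160. The log2 difference of Cdcp1 in Cdcp1 vs Pten reversed to 0.0426 with upper quartile scaling and 0.0139 with protein-coding genes only, and ran from −0.191 to 0.0537 with each library left out, with a reversal without Pten library 1. Each library left out in turn, which leaves fewer libraries, gave 4204 to 7242 calls for Pten against wild type, 5987 to 7237 for Trp53 against Pten, 118 to 752 for Erg against Pten, 13 to 754 for Cdcp1 against Pten and 0 to 0 for Timp1 against Pten. Polysome against total RNA gave 0 to 4677 in Cdcp1 and 0 to 0 in Erg and Timp1. Total RNA gave 3421 to 5252 for Cdcp1 against Erg, 1326 to 1954 for Timp1 against Erg and 125 to 896 for Timp1 against Cdcp1, and the 3 translation comparisons 0 to 0. With the replicate number as a block the counts were 1591 for Erg against Pten, 0 for Cdcp1 against Pten, and in total RNA 4963 for Timp1 against Erg and 1324 for Timp1 against Cdcp1. Libraries of Pten and Timp1 share only a number (correlations 0.15, −0.02 and −0.21), as do those of Pten and Cdcp1 (0.15, −0.21 and 0.07), so for these a lost call is no sign of a weaker effect. Erg shares 2 numbers with each of these groups, too few for a pairing. No other count of genes moved by over 1.5 times with the block, but in Cdcp1 against Erg total RNA 4641 of 6211 calls were among the 5931 it gave. With the block and without mouse 2 labelled Cdcp1, polysome against total RNA gave 55 in Erg, 7267 in Cdcp1 and 6 in Timp1, and translation gave 950 for Cdcp1 against Erg and 16 for Timp1 against Cdcp1. With the block and 1 genotype alone it gave 1587 in Erg and 1385 in Timp1. Gene lists depended most on the test: with an estimated correlation 0 were called in every comparison except polysome against total RNA in Erg, with 1. Fry called 7 lists in Erg against Pten, 1 in Cdcp1 against Pten, 0 in Timp1 against Pten, 0, 1 and 0 in polysome against total RNA of Erg, Cdcp1 and Timp1, 12 in Timp1 against Cdcp1 total RNA, and 0 in each translation comparison. In block fits lists called were 16 for Timp1 polysome against total RNA within the genotype, 9 for Timp1 against Erg translation, and without mouse 2 labelled Cdcp1 19, 12 and 23 for translation of Cdcp1 against Erg, Timp1 against Erg and Timp1 against Cdcp1. No called list's median changed sign under RLE, upper quartile scaling, protein-coding genes only or DESeq2. Removing seminal vesicle genes and 50 correlates left 6044, 7613, 953, 135 and 0 calls in the polysome comparisons and 6203, 2642 and 798 in total RNA. Genes that a filter, this removal or the independent filtering and count-distance rules of DESeq2 left without an adjusted p have no value under that setting.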

Other observations

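The tests in this part that use the mouse as a block were chosen after the results were seen, and values of single libraries come from no test.

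Members of several lists moved in both directions in Trp53 against Pten. Matrix metalloproteinases and their inhibitors rose in 11 of 25 and fell in 5 (16 adjusted over the list alone, camera adjusted p = 0.146), with Mmp16 at 3.98 ± 0.47, the stromelysin Mmp11 at 1.64 ± 0.32 and Mmp15 at −3.68 ± 0.49. Timp1 rose by 1.76 ± 0.63 (adjusted p = 0.0364) in Trp53 against Pten and by 4.18 ± 0.72 (adjusted p = 5.8e-04) in Pten against wild type. Wnt and Notch genes rose in 3 of 20 and fell in 7 (12 adjusted over the list alone, camera adjusted p = 0.108), among them the Wnt receptor ligase Rnf43 at −3.49 ± 0.42 and the transcription factor Sp5 at −4.05 ± 0.64. FOXO and PI3K targets fell in 8 of 20 and rose in 2 (10 adjusted over the list alone, camera adjusted p = 0.0549), with the receptor Erbb3 at −3.74 ± 0.48. Nuclear long noncoding RNAs rose in 4 of 10 (4 adjusted over the list alone, camera adjusted p = 0.0339, adjusted p = 0.65 with an estimated correlation). Cdcp1 rose by 1.37 ± 0.45 in Pten against wild type (adjusted p = 0.0308) and changed by −3.62 ± 0.50 in Trp53 against Pten (adjusted p = 5.9e-05) and by −0.65 ± 0.22 in total RNA of the libraries labelled Cdcp1 against Erg (adjusted p = 0.0317). Trp53 rose by 1.14 ± 0.31 in Pten against wild type (adjusted p = 0.0107).

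With the mouse as a block and 1 genotype alone, further single genes differed between polysomes and total RNA. In Erg, the interferon regulator Irf7 changed by −1.37 ± 0.08 (adjusted p = 4.2e-17) and Pabpc1 by −0.87 ± 0.08 (adjusted p = 2.9e-09), while the cytokine gene Mif rose by 0.46 ± 0.06 (adjusted p = 7.3e-07). In Timp1, the RNA-binding protein gene Ybx1 changed by −1.32 ± 0.13 (adjusted p = 1.9e-13), and the histone gene Hist1h4c rose by 0.58 ± 0.12 (adjusted p = 5.5e-04). The errors and p-values of these fits may understate the spread between mice.

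Some genes were near 0 in whole groups or in single mice. Trim12a, of an antiviral family, had 0 counts in 5 of the 6 libraries labelled Cdcp1 and 1 count in the other, 0 in wild-type libraries 10 and 6 and in Pten library 3, and 30.2 to 44.6 CPM in the Erg libraries. Aadacl3 lay at 4.82 to 19.8 CPM in the 6 libraries labelled Cdcp1 and at most 0.141 CPM elsewhere. The ribosomal protein copy Rps3a3 lay at 45.5 to 113 CPM in the 6 Erg libraries and at most 2.63 CPM elsewhere, and Otos at 16.2 to 33.9 CPM and at most 0.255 CPM. The inflammasome pseudogene Nlrp1c-ps had 0 counts in all libraries of wild type, Trp53 and Cdcp1 and in Pten libraries 2 and 3, against 3.07 CPM in Pten library 1 and 1.47 to 5.61 CPM in the Timp1 and Erg libraries. The strain background of the mice was not tested.

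The 3 wild-type mice carried different secretory genes. In library 6, 9530053A07Rik stood at 285359, the transglutaminase Tgm4 at 31440 and Pbsn at 22710 CPM, with Sbp at 222 and the trypsin inhibitor Spink1 at 48.5 CPM. In libraries 10 and 12 Sbp stood at 125683 and 109089 and Spink1 at 78044 and 67314 CPM, with Tgm4 at 0.816 and 30.5 CPM.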
